A study of Mus musculus with 31 samples.

How the data were processed

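Single-cell RNA of 8 sorted cell types from bone marrow (preT cells from thymus) of PolyloxExpress mice was read in 31 libraries of 4 experiments. Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 on mm10. Each deposited table holds counts: the authors deposited 1 table per library with the number of UMIs of each gene in each cell barcode. The tables held 198243 barcodes and 24507 features named by symbol, 5213 of them at 0 in every library. They hold 0 mitochondrial genes, so the limit of 10% mitochondrial UMIs removed no cell. Kept were cells with at least 500 genes and a log10 UMI number at most 3 scaled median absolute deviations over the library's median. This removed 618 cells for few genes and 1248 for many UMIs, and left 196377. No doublet caller was run. The limit on UMIs and an alternative without the top 5% of cells by UMI replace it only in part. The limit removed 0 to 7 cells from a CMP library, so doublets may remain there.

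The cells of a cell type in an experiment were summed, and the experiment was the replicate. The number of mice per experiment and the sort markers are not given in the sources used here. P-values measure the spread over experiments as labelled that remains after the fit takes out shifts shared by the types of an experiment. The 20 sums of the types tested held 24478099 to 264267943 UMIs. After the filter on low counts 15004 genes were tested in each comparison. CPM of the fitted sums, and means of these over an experiment, are TMM-normalised, and those of preT and single libraries are not. Sums were fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood F test) with a term for each cell type and each experiment, which leaves 10 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Log2 fold changes are first type minus second, and a number in parentheses after a gene symbol in the report is this value. GMP, MEP, CLP and proB have 2 experiments each, so their spread leans on that of the other types. The 6 comparisons, the tests, the alternatives and the 24 gene lists were set before the data were examined.

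Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with a correlation estimated for each list, adjusted over the 24 lists of a comparison. The platelet gene listed as Cavin2 is Sdpr in the files. Counts of members past the threshold are given over all genes and adjusted over the list alone. Genes were named by a rule. Among genes past the threshold, with a mean of at least 20 CPM in the higher type and the same direction in every experiment that holds both types, the 8 highest and the 8 lowest log2 fold changes were taken. Predicted genes, ribosomal protein genes, mitochondrial genes and antigen receptor segments were left out. Up to 4 members of each list described with the lowest adjusted p, and the genes of the surface and receptor list, were added. Some genes that the rule chose are not reported here. Fos in MEP against CMP was chosen after its values were seen. Gene positions (mm10) come from GENCODE M21. Where a type had 20 or fewer UMIs of a gene, the ratio of CPM is given with an exact binomial 95% interval.

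Shares of cells were computed for 10 programs of marker genes. Each cell was thinned to 4000 UMIs at random without replacement, cells with fewer were left out (61.1% to 99.2% of a library's cells were kept), and a cell held a program with at least 3 of its UMIs. HSC, MPP and CMP were compared with exact permutation tests over experiments, adjusted over 20 tests. Co-occurrence in CMP is the number of cells with both programs over the number expected from independence within a library, averaged over experiments. The preT library was not tested. Its genes with at least 50 CPM were ranked by their ratio to the higher of CLP and proB of experiment 3, with a floor of 3 counts over the sum of a type in that experiment, and the first 15 are named.

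The pairing of types within an experiment was checked in HSC, MPP and CMP by correlating the deviations of log2 CPM from a type's mean: the 12 same-experiment pairs had r from 0.517 to 0.836, and other pairs from -0.69 to 0.363. The fit was tested on simulated data with 200 changed genes. For MPP against HSC it called 68.7%, 94.0% and 100% of genes changed 1.5-fold, 2-fold and 4-fold with 0 false calls; for GMP against CMP 47.8%, 91.0% and 100% with 1 false call; and for proB against CLP 55.2%, 98.5% and 100% with 6 false calls. In the simulated data the 2 types compared had no experiment effects, and genes varied independently with the spread typical of their level. Only genes of at least 1 CPM were changed. These rates therefore do not cover genes with more spread, correlated genes or experiment effects. Alternatives were the size factors and Wald test of DESeq2 1.42.0, no filter on low counts, no experiment term, all barcodes, library 1 alone, each library as a sample, ribosomal protein genes removed, only the 2 types compared, and each experiment left out. For programs they were other UMI minimums, 2000 UMIs and no thinning. Added after the data were seen were leaving out HSC of experiment 4, leaving out 3 CMP and GMP libraries with much immediate early RNA for their type, the neutrophil program without Prtn3, and 4 other random draws. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for cells and figures. The barcode sequences themselves were not analysed here.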

Results

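Single-cell RNA was measured with the 10x Chromium 3' v3 assay in sorted blood-forming cells of PolyloxExpress mice, a C57BL/6 line that carries an expressed barcode for tracing the descendants of single stem cells. The labels give 31 libraries of 8 cell types in 4 experiments. HSC (hematopoietic stem cells, 7 libraries), MPP (multipotent progenitors, 6) and CMP (common myeloid progenitors, 5) were in all 4 experiments. CLP (common lymphoid progenitors, 3 libraries) and proB (early B lineage cells, 2) were in experiments 1 and 3, and GMP (granulocyte and monocyte progenitors, 4) and MEP (megakaryocyte and erythroid progenitors, 3) in experiments 2 and 4. The 1 preT library (early T lineage cells, thymus) was in experiment 3. A library held 2785 to 9579 kept cells with a median of 5138 to 16456 UMIs per cell, and from 24478099 to 132298188 UMIs in all. Levels are CPM of cells summed by cell type and experiment, given as mean ± SD over experiments, so n is the number of experiments.

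MPP against HSC asks what separates the stem cells that the barcodes trace from their nearest multipotent descendants, in 4 experiments each. In MPP, stem cell and megakaryocyte genes were lower, and lymphoid, cell cycle and respiratory chain genes were higher. Dntt, the DNA polymerase that adds bases at antigen receptor joints (chromosome 19, 41029275 to 41059525), was at 365 ± 124 CPM in MPP (SD, n = 4) and 7.48 ± 3.37 CPM in HSC (n = 4), log2 fold change 5.50 (SE 0.36), edgeR adjusted p = 1.36e-08. Cd48, a surface protein used to tell HSC from progenitors (chromosome 1, 171682009 to 171705258), was at 125 ± 38.1 CPM in MPP and 7.15 ± 2.57 CPM in HSC, log2 fold change 4.15 (SE 0.12), edgeR adjusted p = 8.66e-12. Slamf1, the stem cell surface marker CD150 (chromosome 1, 171767127 to 171801184), was at 0.186 ± 0.0258 CPM in MPP and 9.10 ± 1.25 CPM in HSC, log2 fold change -5.61 (SE 0.25), edgeR adjusted p = 5.75e-10. Both proteins are commonly used to sort these types; the sort markers are not given in the sources used here, so the sort itself could have set these 2 differences.

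The HSC identity list was lower in MPP throughout: 30 of 30 genes fell (the same adjusted over the list alone). For HSC identity genes, camera gave adjusted p = 9.19e-21, and adjusted p = 0.124 with an estimated correlation. Among its members were Mllt3, a chromatin factor of stem cell maintenance (log2 fold change -2.61, SE 0.098), Nupr1 (log2 fold change -5.32, SE 0.22) and the transcription factor Tcf15 (log2 fold change -3.61, SE 0.17). Socs2, a brake on cytokine signalling, fell as well (log2 fold change -3.54, SE 0.23), and its HSC value was 60.7 CPM in experiment 4 and at most 24.1 CPM in the others. Outside the lists, genes that fell include Tgm2 (-5.10), Clec1a (-4.88), the retinal dehydrogenase Aldh1a1 (-4.73), Grb10 (-4.09) and Abcg3 (-3.48), each as a log2 fold change. Of the megakaryocyte list, 18 of 21 genes fell and 1 rose (1 higher and 19 lower adjusted over the list alone). For megakaryocyte genes, camera gave adjusted p = 9.46e-08, and adjusted p = 0.301 with an estimated correlation. Sdpr, a caveolar protein of platelets, had 20 UMIs over all MPP sums and 6265 in HSC, and was 355-fold lower (95% counting interval 229.6 to 581). Pf4, a platelet granule chemokine, was at 76.7 ± 29.3 CPM in HSC and 7.44 ± 3.39 CPM in MPP, and Vwf, the platelet adhesion factor, had a log2 fold change of -4.95 (SE 0.35).

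Of the early lymphoid list, 16 of 20 genes rose in MPP and 1 fell (the same adjusted over the list alone). For early lymphoid genes, camera gave adjusted p = 5.26e-09, and adjusted p = 0.126 with an estimated correlation. They include Satb1, a chromatin organiser (log2 fold change 2.58, SE 0.084), the recombinase Rag1 (1.71 against 0.0951 CPM), Notch1 (1.38) and the interleukin 7 receptor Il7r (5.53). The B cell list rose in 12 and fell in 0 of 21 genes (the same adjusted over the list alone). For B cell genes, camera gave adjusted p = 0.00251, and adjusted p = 0.342 with an estimated correlation. In the T cell list 9 of 20 genes rose, Arpp21 among them (4.67), and 2 fell (the same adjusted over the list alone). For T cell genes, camera gave adjusted p = 0.0161, and adjusted p = 0.610 with an estimated correlation. The share of cells with at least 3 UMIs of the lymphoid program was 22.8% ± 7.30 in MPP and 0.498% ± 0.172 in HSC (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0357), with 0.0204% in GMP, which should lack it. In experiment 4, MPP stood apart in lymphoid genes: Il7r was at 30.1 CPM and Ly6d at 14.8 CPM, and in the other experiments they reached at most 6.70 and 4.91 CPM. Without experiment 4 the log2 fold change of Il7r was 6.29, and without HSC of experiment 4 it was 6.53.

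Cell cycle genes rose together. All 20 S phase genes were higher in MPP, Uhrf1 (1.38) and the nucleotide reductase Rrm2 (1.83) among them (the same adjusted over the list alone). For S phase genes, camera gave adjusted p = 1.84e-21, and adjusted p = 0.126 with an estimated correlation. All 20 G2/M genes were higher too, such as Aurkb (2.04) and Top2a (1.89), both of chromosome segregation (the same adjusted over the list alone). For G2/M phase genes, camera gave adjusted p = 1.67e-15, and adjusted p = 0.309 with an estimated correlation. Cells with the G2/M program made up 25.6% ± 6.89 of MPP and 7.01% ± 0.795 of HSC (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0357). Oxidative phosphorylation rose in 19 of 21 genes, with Ndufa4 (0.92) and cytochrome c, Cycs (0.85) (20 higher and 0 lower adjusted over the list alone). For oxidative phosphorylation genes, camera gave adjusted p = 6.79e-06, and adjusted p = 0.425 with an estimated correlation. Ribosome biogenesis rose in 16 of 20 genes, Nhp2 among them (0.65), and its 1 lower member was Mycn (-1.73; 17 higher and 1 lower adjusted over the list alone). For ribosome biogenesis genes, camera gave adjusted p = 0.00334, and adjusted p = 0.842 with an estimated correlation. Cholesterol synthesis fell in 11 of 14 genes, Msmo1 (-0.74) and Sqle (-0.57) among them (the same adjusted over the list alone). For cholesterol synthesis genes, camera gave adjusted p = 0.00230, and adjusted p = 0.416 with an estimated correlation.

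Some neutrophil granule genes were also higher in MPP: Mpo, myeloperoxidase (log2 fold change 4.57, SE 0.32), Ctsg, cathepsin G (log2 fold change 4.93, SE 0.86), and Elane, neutrophil elastase (log2 fold change 3.82, SE 0.86, edgeR adjusted p = 0.00163). Prtn3, proteinase 3, was at 372 to 573 CPM (without TMM factors) in the HSC libraries and 296 to 530 CPM in the MPP libraries, and did not pass (log2 fold change -0.055, edgeR adjusted p = 0.852). The neutrophil list as a whole had 7 genes higher, 1 lower and 12 past neither bound (the same adjusted over the list alone). For neutrophil genes, camera gave adjusted p = 0.0544, and adjusted p = 0.855 with an estimated correlation. Without HSC of experiment 4, 12 of its genes were higher and 1 lower. These 3 genes also stood apart in HSC of experiment 4, with TMM-normalised values of 10.6 CPM of Ctsg, 15.3 CPM of Mpo and 11.4 CPM of Elane, and at most 0.324, 3.77 and 0.665 CPM in the other HSC experiments. Without HSC of experiment 4, the log2 fold change was 7.75 for Ctsg and 5.82 for Elane. With all deposited barcodes kept, the log2 fold changes were 2.05 and 0.64 and neither passed; adjusted p over all alternatives ran from 4.93e-09 to 0.208 for Ctsg and from 1.12e-06 to 0.735 for Elane. Without experiment 3, Ctsg was at 4.32 and Elane at 2.82. Cst7, a protease inhibitor (23.7 against 1.02 CPM), and Cox6a2, a muscle form of a cytochrome oxidase subunit (7.69), rose as well, the latter with 57.7 CPM in MPP of experiment 4 and at most 10.6 CPM in the others.

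Among surface and receptor genes, 7 rose and 7 fell of 18 (the same adjusted over the list alone). For surface and receptor genes, camera gave adjusted p = 0.775, and adjusted p = 0.866 with an estimated correlation. Flt3 (1.77) and Cd34 (1.03) rose, Cd9 (-1.48) and Kit (-0.37) fell, and Ptprc (CD45) was at 111 and 109 CPM (edgeR adjusted p = 0.794). The lists erythroid (10 lower, 1 higher of 22) and interferon response (8 lower, 1 higher of 18) did not pass as lists. For erythroid and interferon response genes, camera gave adjusted p = 0.0544 and 0.201, and 0.855 for both with an estimated correlation. In all, edgeR called 7945 of 15004 genes, 3802 higher and 4143 lower in MPP, of which 850 and 1541 differed by a log2 fold change of at least 1. The call of Kit was lost without the experiment term, at a log2 fold change of -0.34 (edgeR adjusted p from 7.76e-05 to 0.278 over all alternatives).

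CMP against MPP asks which lineage genes appear in the sorted myeloid progenitors, again in 4 experiments each. Megakaryocyte, erythroid and monocyte genes and the granule gene Mpo were higher in CMP, and stem cell, lymphoid and interferon genes were lower. Gata1, the erythroid and megakaryocyte transcription factor (chromosome X, 7959260 to 7978071), was at 30.4 ± 3.605 CPM in CMP (SD, n = 4) and 0.416 ± 0.175 CPM in MPP (n = 4), log2 fold change 6.17 (SE 0.23), edgeR adjusted p = 6.57e-11. Mpo (chromosome 11, 87793581 to 87804413) was at 1238 ± 328 CPM in CMP and 124 ± 57.1 CPM in MPP, log2 fold change 3.39 (SE 0.29), edgeR adjusted p = 1.46e-07. Ly6a, the stem cell antigen Sca-1, was at 5.76 ± 1.30 CPM in CMP and 119 ± 17.7 CPM in MPP, log2 fold change -4.38 (SE 0.23), edgeR adjusted p = 1.10e-09. Sca-1 is also a common sort marker, so the sort could have set this difference.

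Of the megakaryocyte list 15 of 21 genes rose and 2 fell (the same adjusted over the list alone). For megakaryocyte genes, camera gave adjusted p = 1.80e-07, and adjusted p = 0.346 with an estimated correlation. Sdpr had 12213 UMIs in CMP and 20 in MPP, 450.1-fold higher (95% counting interval 291 to 737), and the platelet receptor genes Gp1bb (log2 fold change 6.54, SE 0.22), Treml1 (5.17) and Itga2b (2.90) rose with it. Of the erythroid list 18 of 22 rose and 1 fell (the same adjusted over the list alone), with Car1, a carbonic anhydrase (log2 fold change 6.32, SE 0.67), Tspo2 (6.36), the water channel Aqp1 (5.40), the erythropoietin receptor Epor (5.20) and Icam4 (2.49). For erythroid genes, camera gave adjusted p = 1.23e-07, and adjusted p = 0.346 with an estimated correlation. Car1 was at 9.63 CPM in MPP of experiment 3 and at most 2.30 CPM in the others, and its log2 fold change without experiment 3 was 7.19. Mfsd2b, a sphingolipid transporter (6.74), and Csrp3 (6.10) stood outside the lists. The monocyte list rose in 13 and fell in 2 of 17 genes (the same adjusted over the list alone), with F13a1 (5.89), Ly86 (4.63), Ms4a6c (3.08) and Irf8, a monocyte and dendritic cell transcription factor (2.52). For monocyte genes, camera gave adjusted p = 0.00361, and adjusted p = 0.526 with an estimated correlation.

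The neutrophil list had 9 genes higher and 3 lower of 20, Igsf6 (4.78) and Mpo among the higher ones. Of its genes of mature neutrophils, S100a8 was at 88.8 CPM and Ngp at 20.1 CPM in MPP of experiment 3, and at 48.4 and 21.003 CPM in library 1 and 18.1 and 0.218 CPM in library 2 of MPP of experiment 2. The MPP libraries of experiments 1 and 4 held at most 15.8 CPM of S100a8 and 0.264 CPM of Ngp, and the CMP libraries at most 23.04 and 9.90 CPM. Its median log2 fold change was -0.47, while its mean, 0.65, and its test pointed up (the same adjusted over the list alone). For neutrophil genes, camera gave adjusted p = 0.243, and adjusted p = 0.816 with an estimated correlation. The basophil, mast cell and eosinophil list had 7 higher and 1 lower of 17 (the same adjusted over the list alone), with the mast cell protease Cpa3 (3.99) and the interleukin 33 receptor Il1rl1 (4.94) higher. For basophil, mast cell and eosinophil genes, camera gave adjusted p = 0.136, and adjusted p = 0.779 with an estimated correlation. Of the interferon response list 17 of 18 genes fell, Ifi44 (-2.66), Rtp4 (-2.06) and Irf7 (-2.03) among them (the same adjusted over the list alone). For interferon response genes, camera gave adjusted p = 3.91e-09, and adjusted p = 0.198 with an estimated correlation. The early lymphoid list fell in 17 and rose in 1 of 20 (the same adjusted over the list alone), with Rag1 (-3.92), Lax1 (-3.65) and the cytokine Ltb (-3.40). For early lymphoid genes, camera gave adjusted p = 1.39e-07, and adjusted p = 0.198 with an estimated correlation. The B cell list had 13 lower and 2 higher of 21 (the same adjusted over the list alone), and the T cell list 10 lower and 1 higher of 20 (0 higher and 10 lower adjusted over the list alone). For B cell and T cell genes, camera gave adjusted p = 0.0103 and 0.00578, and 0.526 for both with an estimated correlation.

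The HSC identity list fell in 19 and rose in 6 of 30 genes (the same adjusted over the list alone). For HSC identity genes, camera gave adjusted p = 0.0254, and adjusted p = 0.644 with an estimated correlation. Procr fell (-2.94), and Slamf1, which megakaryocyte and erythroid precursors also express, rose (4.55). Wfdc18 (-4.58), the RNA helicase Ddx4 (-4.01), Nkx2-3 (-3.55), Myl10 (-3.45) and Mn1 (-3.28) fell outside the lists. S phase genes rose in 19 of 20, Mcm2 at 0.52 (the same adjusted over the list alone), and G2/M genes rose in 18 and fell in 1 of 20, Ccnb2 at 0.94 (the same adjusted over the list alone). For S phase and G2/M phase genes, camera gave adjusted p = 1.03e-04 and 0.00187, and 0.526 and 0.644 with an estimated correlation. Oxidative phosphorylation rose in 19 of 21, Cycs at 0.91 and Ndufb7 at 0.56 (the same adjusted over the list alone), ribosome biogenesis in 18 of 20 (the same adjusted over the list alone), and glycolysis in 10 of 13 (the same adjusted over the list alone). For oxidative phosphorylation genes, camera gave adjusted p = 9.80e-08, and adjusted p = 0.413 with an estimated correlation. For ribosome biogenesis genes, camera gave adjusted p = 1.87e-04, and adjusted p = 0.526 with an estimated correlation. For glycolysis genes, camera gave adjusted p = 0.00249, and adjusted p = 0.526 with an estimated correlation. The surface and receptor list had a median of -0.51 and a mean of 0.39, and its test pointed up (7 higher, 10 lower; the same adjusted over the list alone). For surface and receptor genes, camera gave adjusted p = 0.943, and adjusted p = 0.971 with an estimated correlation. In it Flt3 (-2.10), Cd34 (-0.63) and Kit (-0.24) fell, and Cd9 (1.47) and Fcgr3 (3.63) rose. edgeR called 9186 of 15004 genes, 4626 higher and 4560 lower in CMP, with 747 and 1779 at a log2 fold change of at least 1. The call of Kit was lost without the experiment term and without experiment 2, at log2 fold changes of -0.233 and -0.235, and its adjusted p ran from 0.000473 to 0.435 over all alternatives.

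Shares of cells with at least 3 UMIs of a program, after each cell was thinned to 4000 UMIs, put these differences in cells. The erythroid program was in 16.0% ± 1.53 of CMP and 0.1002% ± 0.0434 of MPP, with 91.9% in MEP and 0.113% in proB, which should lack it. The megakaryocyte program was in 4.55% ± 2.17 of HSC, 0.177% ± 0.0842 of MPP and 8.27% ± 2.20 of CMP, and 0.0121% of CLP. It was also in 2.35% of GMP and 1.64% of MEP. The monocyte program was in 20.7% ± 6.29 of CMP and 1.24% ± 0.717 of MPP, with 0.0735% in preT. Other lymphoid types held it more often, 53.0% of CLP and 9.08% of proB, and GMP was at 41.1%. The basophil, mast cell and eosinophil program was in 10.6% ± 3.48 of CMP and 0.354% ± 0.121 of MPP, with 0.156% in CLP. The HSC program was in 77.3% ± 5.12 of HSC, 28.3% ± 8.81 of MPP and 3.84% ± 1.51 of CMP, with 0.163% in proB. The neutrophil program was in 29.5% ± 7.68 of HSC, 33.8% ± 9.92 of MPP and 60.3% ± 4.20 of CMP, and without Prtn3, left out after the levels were seen, in 0.103% ± 0.168, 5.70% ± 4.17 and 50.7% ± 5.47, with 0.0755% in proB. Experiment 4 raises the first 2 of these means: without Prtn3, HSC was at 0.355% there and at most 0.0308% in the others, and MPP at 11.9% and at most 4.18%. CMP and MPP differed past adjusted p 0.05 in all 10 programs and MPP and HSC in 6 of 10, each such difference at an exact permutation p of 0.0286 (SD, n = 4, two-sided), the smallest p that 4 against 4 can give, and an adjusted p of 0.0357. The neutrophil program depends on the thinning: without it, the program was in 69.2% ± 6.07 of CMP and 65.0% ± 18.3 of MPP (SD, n = 4), 4.12 points apart in place of 26.5, and did not pass (exact permutation adjusted p = 0.752; 0.0336 to 0.752 over its alternatives). The shares of other programs moved too: without thinning, the megakaryocyte program was in 16.4% ± 7.21 of HSC and 12.7% ± 3.15 of CMP, which turns their order, and the HSC program in 61.1% ± 22.7 of MPP. Paired by experiment, the exact sign-flip p cannot go under 0.125, so no program can pass that test. The B and T cell programs were in under 0.4% of these 3 types, and their calls changed with the random draw of the thinning.

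**Figure D1:**
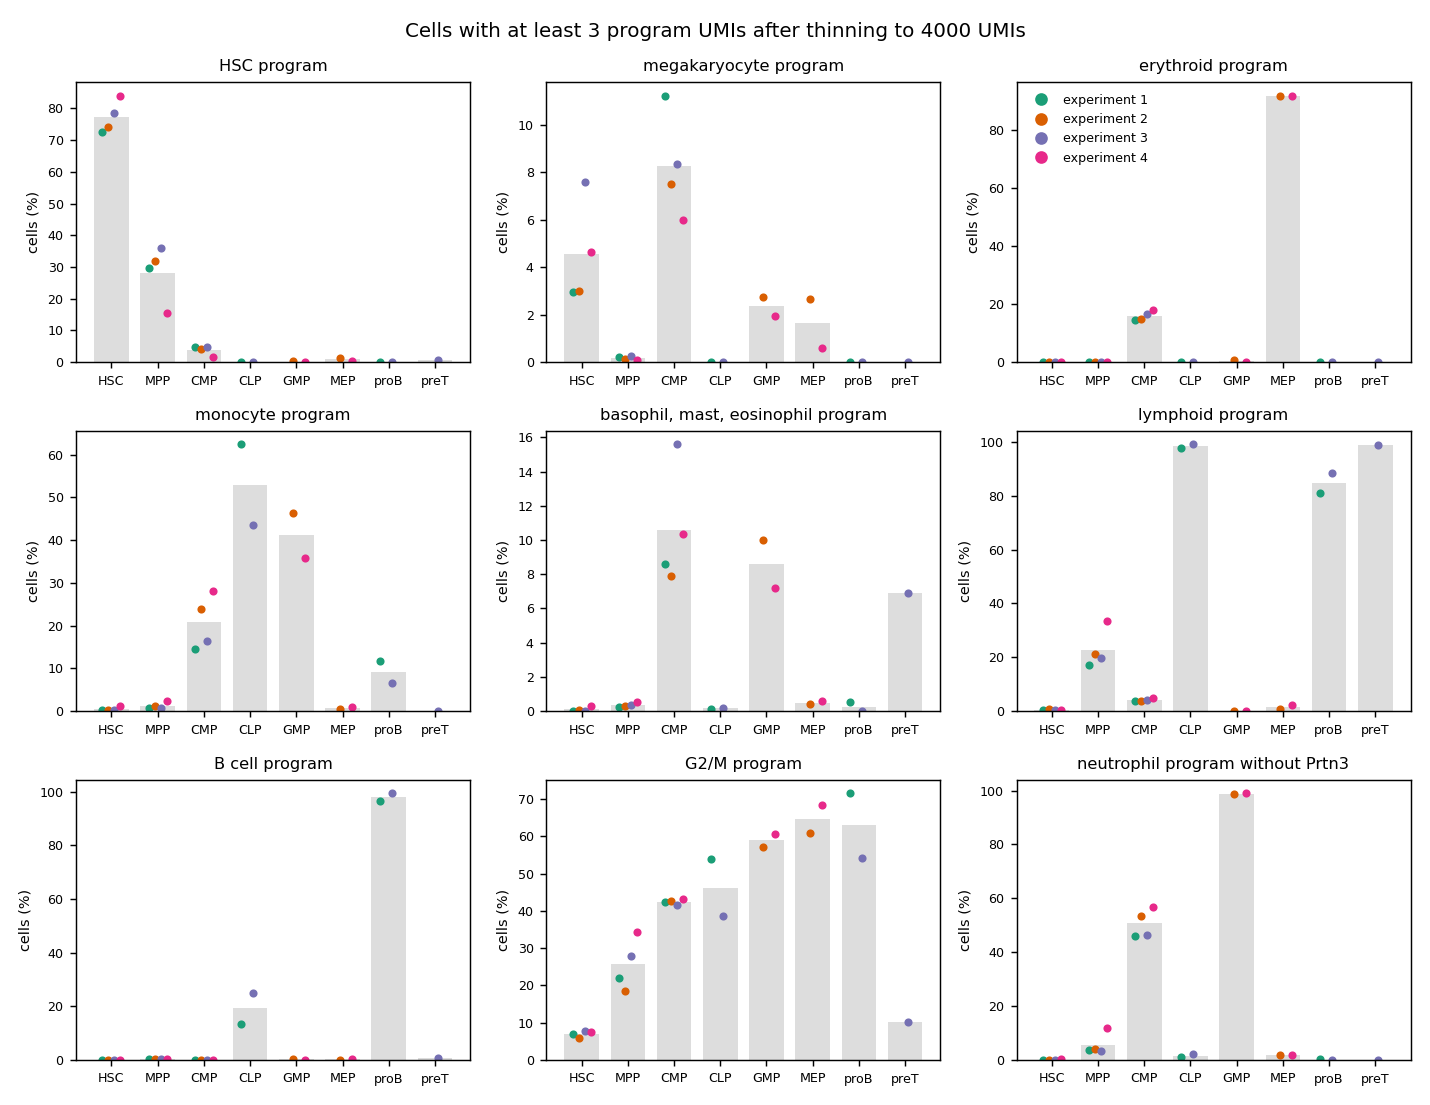
Percent of cells of each sorted type with at least 3 UMIs of a program after thinning to 4000 UMIs; bars are means and points are experiments. The HSC program falls from 77.3% of HSC to 28.3% of MPP and 3.84% of CMP, and the erythroid program is in 16.0% of CMP and 91.9% of MEP.

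Within CMP, most lineage programs were in different cells. Cells with both the megakaryocyte and the monocyte program were 0.0435 ± 0.0161 times as frequent as independence within a library predicts (SD, n = 4 experiments), and the ratio was 0.187 ± 0.0112 for the megakaryocyte with the neutrophil program and 0.144 ± 0.0135 for the erythroid with the neutrophil program. The megakaryocyte and erythroid programs shared cells at a ratio of 0.398 ± 0.0926, and the erythroid with the basophil, mast cell and eosinophil program at 0.427 ± 0.0383. The neutrophil program was found with the monocyte program at 1.61 ± 0.114 and with the basophil, mast cell and eosinophil program at 1.29 ± 0.0816. Of the 10 pairs, 8 were under 1 and 2 over 1 in 4 of 4 experiments. When the programs were shuffled over cells of a library, mean ratios were 0.891 to 1.01. The ratio of the megakaryocyte with the erythroid program was 1.08 when 2 UMIs were enough, so its direction depends on that choice. With at least 2 and at least 5 UMIs, the megakaryocyte with the neutrophil program was at 0.457 and 0.0642, and the erythroid with the neutrophil program at 0.351 and 0.0482. Thinning to 2000 UMIs put these 2 pairs at 0.0939 and 0.0634, so the sizes of the ratios depend on the UMI limits. They also depend on the cells with the most UMIs. Without the top 5% of cells by UMI, the megakaryocyte with the monocyte program was at 0.0122, in place of 0.0435. The erythroid with the monocyte program was then at 0.0293, in place of 0.0591. Doublets can hold both programs and raise these ratios. No doublet caller was run, so how many of the cells with both programs are doublets is not known.

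**Figure D2:**
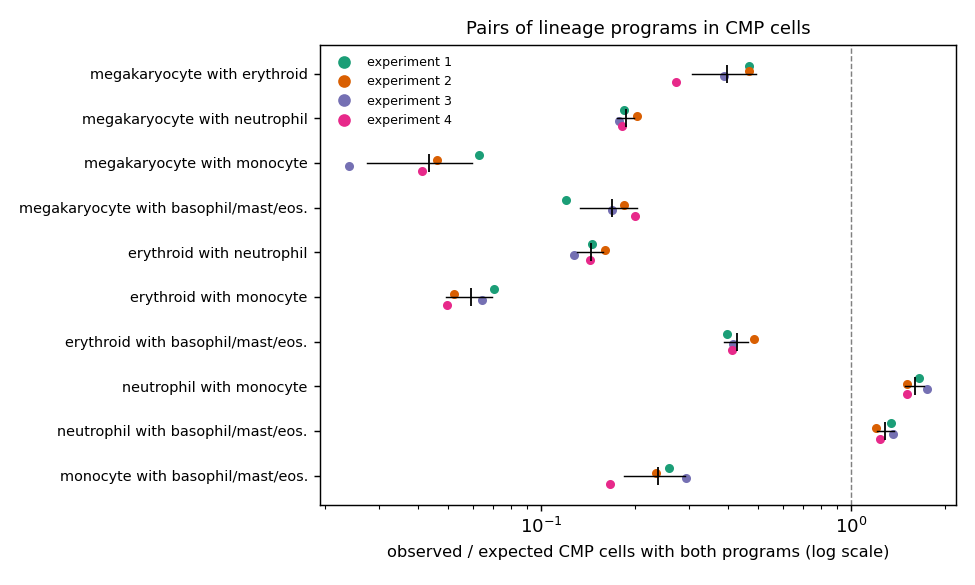
Ratio of observed to expected CMP cells that hold both of a pair of programs (log axis, dashed line at 1); points are experiments, and bars are the mean and its SD. The neutrophil program sits over 1 with the monocyte program (1.61) and with the basophil, mast cell and eosinophil program (1.29), and the other 8 pairs sit under 1.

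CLP against MPP asks what marks the sorted lymphoid progenitors, with 2 experiments of CLP and 4 of MPP. B lineage and monocyte list genes were higher in CLP, and stem cell, megakaryocyte and glycolytic genes and 7 of 20 neutrophil genes were lower. Ly6d, a surface marker of B-primed lymphoid progenitors (chromosome 15, 74762056 to 74763620), was at 3426 ± 659.7 CPM in CLP (SD, n = 2) and 7.08 ± 5.14 CPM in MPP (n = 4), log2 fold change 9.68 (SE 0.73), edgeR adjusted p = 3.74e-08. Ebf1, a transcription factor of B cell commitment (chromosome 11, 44617317 to 45008091), was at 55.0 ± 15.2 CPM in CLP and 0.438 ± 0.449 CPM in MPP, log2 fold change 7.91 (SE 0.35), edgeR adjusted p = 1.64e-10.

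All 21 B cell genes tested rose (the same adjusted over the list alone), among them Cecr2 (log2 fold change 8.15, SE 0.24), the surrogate light chain genes Vpreb2 (8.57), Vpreb3 (7.76) and Igll1 (7.98), Cd79a of the B cell receptor (8.29), the kinase Blk (7.93), Blnk (5.77) and Akap12 (4.93). For B cell genes, camera gave adjusted p = 3.55e-15, and adjusted p = 0.0197 with an estimated correlation. In MPP of experiment 4, Ebf1 was at 1.11, Vpreb2 at 0.735, Igll1 at 0.603 and Blk at 0.433 CPM, and in its other experiments they were at most 0.234, 0.1303, 0.0760 and 0.234 CPM. Igll1 was at 8.87 without experiment 4. The B cell program was in 19.2% ± 8.13 of CLP cells (SD, n = 2), 0.229% of MPP and 0.152% of GMP. Of the early lymphoid list 14 rose and 3 fell of 20 (the same adjusted over the list alone), with Rag1 (6.06), Il7r (5.93) and Notch1 (1.52) higher. For early lymphoid genes, camera gave adjusted p = 3.66e-04, and adjusted p = 0.455 with an estimated correlation. In the T cell list 10 rose, Cd247 (3.25) and Arpp21 (3.17) among them, and 4 fell of 20 (10 higher and 5 lower adjusted over the list alone). For T cell genes, camera gave adjusted p = 0.0179, and adjusted p = 0.466 with an estimated correlation. The lymphoid program was in 98.3% of CLP cells and 0.0204% of GMP.

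Monocyte list genes also rose, 10 of 17 with 2 lower (the same adjusted over the list alone): Irf8, which lymphoid cells also express (log2 fold change 5.16, SE 0.22), Ly86 (6.79) and Mpeg1 (5.46). For monocyte genes, camera gave adjusted p = 0.0108, and adjusted p = 0.563 with an estimated correlation. The monocyte program was in 53.0% ± 13.3 of CLP, 41.1% of GMP and 0.0735% of preT. Csf1r (4.25 against 31.6 CPM) and Fcgr3 (0.963 against 209 CPM) were lower in CLP than in GMP. Siglech, a marker of plasmacytoid dendritic cells, was at 173 ± 66.1 CPM in CLP and 0.400 ± 0.254 CPM in MPP (log2 fold change 9.08, SE 0.47), and at 10.16 without experiment 1 and 8.41 without experiment 3; Tcf4, a transcription factor of the same cells, was at 1.12. The dendritic cell and MHC class II list had a median of -0.57 but a mean of 1.07, and its test pointed up (4 higher, 3 lower of 13; 4 higher and 4 lower adjusted over the list alone). For dendritic cell and MHC class II genes, camera gave adjusted p = 0.400, and adjusted p = 0.723 with an estimated correlation. S phase rose in 19 and G2/M in 20 of 20 genes (both the same adjusted over the list alone). G2/M includes Ccnb2 (1.29) and Aurkb (1.27). For S phase and G2/M phase genes, camera gave adjusted p = 2.89e-06 and 6.26e-08, and 0.455 for both with an estimated correlation. Cholesterol synthesis rose in 9 of 14, Fdps at 1.18 (the same adjusted over the list alone). For cholesterol synthesis genes, camera gave adjusted p = 0.00712, and adjusted p = 0.455 with an estimated correlation. Oxidative phosphorylation had 11 higher and 1 lower of 21 (the same adjusted over the list alone). For oxidative phosphorylation genes, camera gave adjusted p = 0.00972, and adjusted p = 0.563 with an estimated correlation.

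The HSC identity list fell in 25 and rose in 1 of 30 (the same adjusted over the list alone), with Hlf, a stem cell transcription factor (-5.45), and Pdzk1ip1 (-5.77). For HSC identity genes, camera gave adjusted p = 8.40e-12, and adjusted p = 0.255 with an estimated correlation. Procr had 14 UMIs in CLP and 6576 in MPP, 262-fold lower (95% counting interval 156 to 479). The megakaryocyte list fell in 15 and rose in 1 of 21 (the same adjusted over the list alone). For megakaryocyte genes, camera gave adjusted p = 1.90e-05, and adjusted p = 0.455 with an estimated correlation. The erythroid list had 11 lower, Car2 (-3.94) among them, and 2 higher of 22 (the same adjusted over the list alone); the higher ones include Tfrc, the transferrin receptor that dividing cells use (3.54). For erythroid genes, camera gave adjusted p = 0.0230, and adjusted p = 0.563 with an estimated correlation. The neutrophil list fell in 7 of 20, Prtn3 (-4.35) and Csf3r (-3.55) among them, and 13 passed neither way (the same adjusted over the list alone). For neutrophil genes, camera gave adjusted p = 0.0108, and adjusted p = 0.563 with an estimated correlation. In it, S100a8 was at 86.4 CPM in CLP library 2 of experiment 3, and at 5.85 and 0.603 CPM in the other CLP libraries. Glycolysis fell in 8 of 13, Aldoa (-1.44) and Hk1 (-1.07) among them (the same adjusted over the list alone), and the macrophage list in 8 of 11 with 1 higher, Hmox1 at -2.63 (the same adjusted over the list alone). For glycolysis and macrophage genes, camera gave adjusted p = 0.00153 and 3.66e-04, and 0.460 and 0.455 with an estimated correlation. Outside the lists Sdsl (-6.31), Myct1 (-6.21), Pcp4l1 (-6.09), Gng11 (-5.94), Clec4e (-5.79) and Tnip3 (-5.63) fell. Of the surface and receptor list 9 fell and 6 rose of 18 (the same adjusted over the list alone), with Kit (-2.51) and Cd34 (-1.75) lower, and Flt3 at 275 ± 24 CPM in CLP and 233 ± 20.0 CPM in MPP (edgeR adjusted p = 0.356). For surface and receptor genes, camera gave adjusted p = 0.0230, and adjusted p = 0.460 with an estimated correlation. Flt3 passed with only the 2 types compared, at a log2 fold change of 0.27 (edgeR adjusted p over its alternatives from 0.0294 to 0.604). edgeR called 7598 of 15004 genes, 3878 higher and 3720 lower in CLP, with 1164 and 1801 at a log2 fold change of at least 1. Without experiment 1, which leaves 1 CLP sum whose spread is assumed to be that of the other types, the count was 4946.

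proB against CLP asks what the next step of the B lineage adds, in 2 experiments each. B cell genes rose further, and Cd34, monocyte, early lymphoid and cholesterol synthesis genes were lower. Lef1, a transcription factor of the Wnt pathway (chromosome 3, 131110471 to 131224356), was at 421 ± 19.1 CPM in proB (SD, n = 2) and 1.92 ± 0.147 CPM in CLP (n = 2), log2 fold change 7.79 (SE 0.31), edgeR adjusted p = 1.58e-10. Cd34 (chromosome 1, 194938819 to 194961279) was at 1.14 ± 0.0718 CPM in proB and 154 ± 18.03 CPM in CLP, log2 fold change -7.06 (SE 0.14), edgeR adjusted p = 5.53e-14.

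Of the B cell list 19 of 21 genes rose (the same adjusted over the list alone), with Cd79b (log2 fold change 3.37, SE 0.13), Cd24a (2.14) and Akap12 (4.24). For B cell genes, camera gave adjusted p = 1.09e-16, and adjusted p = 0.0160 with an estimated correlation. The B cell program was in 98.1% ± 1.96 of proB cells (SD, n = 2), 19.2% ± 8.13 of CLP and 0.0659% of HSC. Ms4a1 (CD20) had 5441 UMIs in proB and 2 in CLP, a ratio of CPM of 5268 (95% counting interval 1458 to 43514). It is on the mature B and plasma cell list, of which 6 rose and 1 fell of 8 (the same adjusted over the list alone), and on which Mzb1, of antibody secretion, rose as well (3.77). For mature B and plasma cell genes, camera gave adjusted p = 0.00302, and adjusted p = 0.0511 with an estimated correlation. Outside the lists Ttll11 had 4116 and 8 UMIs, a ratio of CPM of 996 (interval 505 to 2309), Tnfrsf19 4192 and 18 (ratio 451.0, interval 285 to 762), and Smtnl2 2523 and 11 (ratio 444, interval 248 to 891); without experiment 3 the fitted log2 fold changes of Ms4a1, Tnfrsf19 and Smtnl2 went from 12.47, 8.89 and 8.83 to 15.40, 10.29 and 10.46. The complexin gene Cplx2 (8.30), Sit1 (7.44) and Rsph1 (7.24) rose too. Among lineage transcription factors (9 higher, 13 lower of 26; the same adjusted over the list alone), Id3 (4.16) and Zfpm1 (3.40) rose and Hoxa9 fell (-2.72). For lineage transcription factors, camera gave adjusted p = 0.0856, and adjusted p = 0.640 with an estimated correlation.

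The early lymphoid list fell in 12 and rose in 5 of 20 genes (the same adjusted over the list alone), with Cd27 (-3.58), Notch1 (-2.45) and Satb1 (-2.19) lower and Tcf3, the E protein of B cell commitment, higher (1.64). For early lymphoid genes, camera gave adjusted p = 0.0181, and adjusted p = 0.640 with an estimated correlation. The monocyte list fell in 11 and rose in 1 of 17 (the same adjusted over the list alone), with Irf8 (-2.66), Fcer1g (-4.16) and Cd68 (-2.38), and Siglech fell with it (-4.35). For monocyte genes, camera gave adjusted p = 0.0140, and adjusted p = 0.762 with an estimated correlation. All 14 cholesterol synthesis genes fell, Insig1 among them (-1.10; the same adjusted over the list alone). For cholesterol synthesis genes, camera gave adjusted p = 0.0135, and adjusted p = 0.640 with an estimated correlation. G2/M genes rose in 12 of 20, Ccnb1 (1.43) and Cdc20 (1.10) among them (13 higher and 0 lower adjusted over the list alone), and oxidative phosphorylation in 18 of 21, Ndufs6 at 0.79 (19 higher and 0 lower adjusted over the list alone). For G2/M phase and oxidative phosphorylation genes, camera gave adjusted p = 0.0235 and 1.93e-04, and 0.841 and 0.640 with an estimated correlation. Of other genes that fell, Mpo (-6.45) is a granule gene, and Pdgfrb (-5.24) is on the stroma and endothelium list (3 lower, 1 higher of 10). For stroma and endothelium genes, camera gave adjusted p = 0.296, and adjusted p = 0.841 with an estimated correlation. Gcnt2 (-6.34), Mn1 (-5.64), Kcnk12 (-5.51) and Hmga2 (-5.37) are on none. In the surface and receptor list 7 fell and 4 rose of 18 (the same adjusted over the list alone), Flt3 (-4.49) and Kit (-1.15) lower and Cd9 (1.46) higher, with Il7r at 309.5 ± 14.6 CPM in proB and 442 ± 39.0 CPM in CLP (edgeR adjusted p = 0.231). For surface and receptor genes, camera gave adjusted p = 0.0178, and adjusted p = 0.640 with an estimated correlation. Il7r passed without experiment 4 and with only the 2 types compared, at -0.51 and -0.497 (edgeR adjusted p over its alternatives from 0.00191 to 0.650). Experiment 4 holds no proB or CLP, so leaving it out changed the test of Il7r only through what the fit draws from other types. With only the 2 types compared, edgeR gave adjusted p = 0.0141 for Il7r. edgeR called 7911 of 15004 genes, 3683 higher and 4228 lower in proB, with 1260 and 1979 at a log2 fold change of at least 1. Each type has 2 sums, and leaving an experiment out moved fold changes, here as log2: without experiment 1, -5.31 for Fcer1g, -6.47 for Kcnk12, -8.28 for Mpo, -6.53 for Pdgfrb, -5.06 for Siglech; without experiment 3, -5.60 for Mpo, -3.76 for Siglech.

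GMP against CMP asks which of the lineage genes of CMP go on in the granulocyte and monocyte branch, with 2 experiments of GMP and 4 of CMP. Neutrophil granule genes, the eosinophil genes Prg2 and Prg3, glycolysis and respiration were higher in GMP, and erythroid, megakaryocyte, early lymphoid, T cell list, interferon and stem cell genes were lower. Elane (chromosome 10, 79886247 to 79888215) was at 9519 ± 736 CPM in GMP (SD, n = 2) and 497 ± 165 CPM in CMP (n = 4), log2 fold change 4.18 (SE 0.85), edgeR adjusted p = 6.90e-04, and at 3.40 without experiment 2. Cebpe, the transcription factor of granule formation (chromosome 14, 54710360 to 54712174), was at 206 ± 14.9 CPM in GMP and 9.05 ± 2.31 CPM in CMP, log2 fold change 4.47 (SE 0.26), edgeR adjusted p = 5.20e-09. Klf1, the erythroid transcription factor (chromosome 8, 84901928 to 84905291), was at 1.99 ± 1.33 CPM in GMP and 31.3 ± 3.51 CPM in CMP, log2 fold change -4.08 (SE 0.35), edgeR adjusted p = 1.71e-07, at -5.06 without experiment 2 and -3.42 without experiment 4.

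The neutrophil list rose in 13 of 20 genes and fell in 0 (the same adjusted over the list alone), with Ms4a3 (log2 fold change 3.69, SE 0.38), Gstm1 (3.27) and the transcription factor Gfi1 (2.15). For neutrophil genes, camera gave adjusted p = 2.56e-04, and adjusted p = 0.434 with an estimated correlation. The neutrophil program without Prtn3 was in 98.8% ± 0.239 of GMP cells (SD, n = 2), 50.7% ± 5.47 of CMP and 0.0755% of proB. Prg2, the eosinophil major basic protein, rose (log2 fold change 6.68, SE 1.33, edgeR adjusted p = 5.96e-04) along with Prg3 (4.81). On their list 4 were higher and 1 lower of 17 (the same adjusted over the list alone). For basophil, mast cell and eosinophil genes, camera gave adjusted p = 0.423, and adjusted p = 0.837 with an estimated correlation. The monocyte list had 4 higher of 17 (3 higher and 0 lower adjusted over the list alone), Ly6c2 among them (log2 fold change 3.61, SE 1.02, edgeR adjusted p = 0.00732), whose call was lost without experiment 2 (log2 fold change 2.80; adjusted p from 1.03e-07 to 0.149 over all alternatives). For monocyte genes, camera gave adjusted p = 0.212, and adjusted p = 0.837 with an estimated correlation. The monocyte program was in 41.1% ± 7.36 of GMP and 20.7% ± 6.29 of CMP. Clec4a2 (5.76), Wfdc21 (5.57), Chst13 (4.88), Sgms2 (4.68) and Gda (4.59) rose outside the lists, and Wfdc21 in CMP was at 0.719 CPM in experiment 2 and at most 0.116 CPM in the others. Log2 fold changes with an experiment left out were, without experiment 2, 5.90 for Prg2, 4.02 for Prg3, 7.66 for Wfdc21; without experiment 4, 4.84 for Wfdc21; without 3 CMP and GMP libraries with much immediate early RNA for their type, a setting added later, Wfdc21 was at 6.77.

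Glycolysis rose in 10 and fell in 1 of 13 genes, Pgam1 (1.27), Pfkp (1.20) and Gpi1 (1.15) among the higher ones (12 higher and 1 lower adjusted over the list alone). For glycolysis genes, camera gave adjusted p = 6.30e-05, and adjusted p = 0.290 with an estimated correlation. Oxidative phosphorylation rose in 19 of 21, Cycs at 0.99 and Ndufs6 at 0.75 (21 higher and 0 lower adjusted over the list alone). For oxidative phosphorylation genes, camera gave adjusted p = 8.28e-08, and adjusted p = 0.290 with an estimated correlation. S phase genes rose in 15 of 20 (16 higher and 0 lower adjusted over the list alone). G2/M genes rose in 4 of 20 (0 adjusted over the list alone). For S phase and G2/M phase genes, camera gave adjusted p = 7.71e-04 and 0.309, and 0.487 and 0.837 with an estimated correlation. The G2/M program was in more cells of GMP, 59.0% ± 2.44 against 42.5% ± 0.644 of CMP (SD, n = 2 and 4, not tested). The erythroid list fell in 16 of 22 and rose in 3 (the same adjusted over the list alone): Car1 (-5.67), Tspo2 (-5.23), Aqp1 (-4.31), Epor (-4.21), Car2 (-3.51) and Hemgn (-3.04) fell and Tfrc rose (1.06). For erythroid genes, camera gave adjusted p = 2.35e-05, and adjusted p = 0.290 with an estimated correlation. The megakaryocyte list fell in 15 of 21, with Gp5 (-2.36) and Plek (-1.64; 0 higher and 16 lower adjusted over the list alone). For megakaryocyte genes, camera gave adjusted p = 1.36e-04, and adjusted p = 0.290 with an estimated correlation. Interferon response fell in 13 of 18, Rtp4 (-2.86) and Ifi44 (-2.88) among them (the same adjusted over the list alone). For interferon response genes, camera gave adjusted p = 3.13e-06, and adjusted p = 0.290 with an estimated correlation. Without an experiment, some fold changes moved by over 1.5-fold, here as log2: without experiment 2, -5.14 for Aqp1, -7.13 for Car1, -5.07 for Epor, -6.92 for Tspo2; without experiment 4, -4.74 for Car1, -4.34 for Tspo2.

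The early lymphoid list fell in 17 and rose in 1 of 20 genes (1 higher and 18 lower adjusted over the list alone), with Dntt at 0.294 ± 0.231 CPM in GMP and 75.6 ± 4.98 CPM in CMP (-8.05, and -9.34 without experiment 2), Lax1 (-4.26) and Bcl11a (-1.71). For early lymphoid genes, camera gave adjusted p = 1.82e-07, and adjusted p = 0.290 with an estimated correlation. The B cell list had 4 higher and 4 lower of 21 (2 higher and 3 lower adjusted over the list alone). For B cell genes, camera gave adjusted p = 0.550, and adjusted p = 0.837 with an estimated correlation. The T cell list fell in 11 of 20, Lat at -2.87 (the same adjusted over the list alone), the HSC identity list in 25 of 30 with 1 higher, Txnip at -1.71 (the same adjusted over the list alone), and the dendritic cell and MHC class II list in 10 of 13 (the same adjusted over the list alone). For T cell and HSC identity genes, camera gave adjusted p = 0.00107 and 1.92e-09, and 0.290 for both with an estimated correlation. For dendritic cell and MHC class II genes, camera gave adjusted p = 0.00317, and adjusted p = 0.290 with an estimated correlation. Wfdc17 (-4.32, and -4.99 without experiment 2), Mfsd2b (-3.63) and Gimap6 (-3.54) fell outside the lists. Lineage transcription factors fell in 16 and rose in 5 of 26, Gfi1b at -3.27 (the same adjusted over the list alone). For lineage transcription factors, camera gave adjusted p = 0.00696, and adjusted p = 0.290 with an estimated correlation. Surface and receptor genes fell in 11 and rose in 2 of 18 (the same adjusted over the list alone): Flt3 (-3.43, and -4.17 without experiment 2) and Cd34 (-0.54) fell, the Fc receptor Fcgr3 rose (3.65), and Csf1r (31.6 against 15.4 CPM, edgeR adjusted p = 0.194) and Ptprc (69.2 against 81.4 CPM, edgeR adjusted p = 0.150) did not pass. For surface and receptor genes, camera gave adjusted p = 7.70e-04, and adjusted p = 0.290 with an estimated correlation. Cd34 and Fcgr3 are common sort markers, so the sort could have set their differences and part of the list result. The log2 fold change of Csf1r was 0.69, with -0.048 without experiment 2. It passed without experiment 4, with only the 2 types compared and with each library as a sample, and edgeR adjusted p over its alternatives ran from 6.20e-04 to 0.964, and for Ptprc from 0.0139 to 0.311. edgeR called 8215 of 15004 genes, 4041 higher and 4174 lower in GMP, with 755 and 1946 at a log2 fold change of at least 1. The count was 5358 without experiment 2, which leaves 1 GMP sum whose spread is assumed to be that of the other types.

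MEP against CMP asks the same of the megakaryocyte and erythroid branch, with 2 experiments of MEP and 4 of CMP. Erythroid genes were higher in MEP, while megakaryocyte, monocyte, immediate early and 12 of 20 neutrophil genes were lower. Sphk1, a sphingosine kinase of red cell precursors (chromosome 11, 116530925 to 116536674), was at 114 ± 40.1 CPM in MEP (SD, n = 2) and 1.00 ± 0.235 CPM in CMP (n = 4), log2 fold change 7.15 (SE 0.36), edgeR adjusted p = 1.62e-10. Cpox, an enzyme of heme synthesis (chromosome 16, 58670292 to 58717636), was at 268 ± 51.0 CPM in MEP and 24.8 ± 2.38 CPM in CMP, log2 fold change 3.33 (SE 0.075), edgeR adjusted p = 9.40e-14. Irf8 (chromosome 8, 120736358 to 120756694) was at 6.95 ± 1.97 CPM in MEP and 197 ± 49.5 CPM in CMP, log2 fold change -5.15 (SE 0.28), edgeR adjusted p = 3.23e-10.

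All 22 erythroid genes tested rose, among them Tfrc (2.57), Fech of heme synthesis (2.17), Ank1 of the red cell skeleton (5.10) and Epor (2.96; the same adjusted over the list alone). For erythroid genes, camera gave adjusted p = 2.64e-08, and adjusted p = 0.559 with an estimated correlation. The erythroid program was in 91.9% ± 0.0110 of MEP (SD, n = 2), 16.0% ± 1.53 of CMP and 0.113% of proB. Outside the lists Tmem56 (log2 fold change 7.42, SE 0.32), the metallothionein Mt2 (6.69), Cldn13 (6.59), Asb17os (6.36), Nxpe2 (6.21), Paqr9 (6.13) and the red cell pyruvate kinase Pklr (5.92) rose. The other pyruvate kinase, Pkm, fell (-3.79); it is on the glycolysis list (3 higher, 6 lower of 13; the same adjusted over the list alone). For glycolysis genes, camera gave adjusted p = 0.271, and adjusted p = 0.796 with an estimated correlation. Megakaryocyte genes fell in 18 and rose in 1 of 21, with Plek (-3.35), Itga2b (-2.77) and Fli1 (-2.35; the same adjusted over the list alone), and the megakaryocyte program was in 1.64% ± 1.47 of MEP and 8.27% ± 2.20 of CMP, with 0.0121% in CLP. For megakaryocyte genes, camera gave adjusted p = 1.60e-04, and adjusted p = 0.611 with an estimated correlation.

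The monocyte list fell in 14 of 17 genes (0 higher and 15 lower adjusted over the list alone), with F13a1 (-6.30), Ly86 (-5.90), Ms4a6c (-5.90) and Ms4a6b (-4.99), and the neutrophil list in 12 of 20 (0 higher and 11 lower adjusted over the list alone), with Ctsg (-5.80), Mpo (-5.68), Csf3r (-4.44), Gfi1 (-4.48) and Cebpa (-4.15). For monocyte and neutrophil genes, camera gave adjusted p = 1.40e-04 and 0.0241, and 0.611 and 0.770 with an estimated correlation. Some genes of mature neutrophils in the list leaned the other way: S100a9 was at 37.2 to 54.7 CPM in the MEP libraries and 1.64 to 38.8 CPM in the CMP libraries, and Camp at 14.1 to 19.3 and 0.1396 to 14.5 CPM. Neither passed (edgeR adjusted p = 0.211 and 0.182). Tifab (-5.89), the hexokinase Hk3 (-5.59) and Serpinf1 (-5.57) fell outside the lists. Immediate early and stress genes fell in 15 of 18, with Ier3 (-1.88), Klf6 (-1.91) and Zfp36 (-2.94; the same adjusted over the list alone). For immediate early and stress genes, camera gave adjusted p = 0.00528, and adjusted p = 0.732 with an estimated correlation. In this group the CMP libraries differed: Fos, singled out after its values were seen, was at 152 CPM in library 1 and 9.68 CPM in library 2 of experiment 2, and at 44.7, 13.2 and 12.7 CPM in experiments 1, 3 and 4. Without 3 CMP and GMP libraries with much immediate early RNA for their type, an alternative added later, 11 genes of the list fell and 1 rose, and the log2 fold change of Fos went from -2.70 to -1.82. Without the experiment term Fos was at -2.09 and did not pass (edgeR adjusted p = 0.0518; 7.75e-06 to 0.0518 over its alternatives), nor did the list (camera adjusted p = 0.107).

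Ribosome biogenesis rose in 18 and fell in 1 of 20 genes, with Ncl (1.17), Nolc1 (1.16) and Rrp9 (1.38; the same adjusted over the list alone). For ribosome biogenesis genes, camera gave adjusted p = 6.40e-05, and adjusted p = 0.611 with an estimated correlation. Oxidative phosphorylation rose in 20 of 21, Ndufs6 (1.07) and Cox5b (0.92) among them (the same adjusted over the list alone), and S phase in 16 of 20, Cdc6 (1.20) and Dut (1.14) among them (the same adjusted over the list alone). For oxidative phosphorylation and S phase genes, camera gave adjusted p = 8.06e-07 and 0.00354, and 0.611 and 0.745 with an estimated correlation. The HSC identity list fell in 23 of 30 (the same adjusted over the list alone); its 1 higher gene was Mllt3 (1.92). For HSC identity genes, camera gave adjusted p = 0.00120, and adjusted p = 0.611 with an estimated correlation. The early lymphoid list fell in 12 and rose in 4 of 20, Satb1 (-3.68) and Cd27 (-3.78) among the lower ones (the same adjusted over the list alone). For early lymphoid genes, camera gave adjusted p = 0.0120, and adjusted p = 0.611 with an estimated correlation. Among lineage transcription factors Spi1, the myeloid regulator PU.1, fell (-3.59; 11 higher, 14 lower of 26). For lineage transcription factors, camera gave adjusted p = 0.156, and adjusted p = 0.732 with an estimated correlation. Surface and receptor genes fell in 12 and rose in 1 of 18, Cd34 at 10.8 against 323 CPM (-4.85), and Kit was at 145 and 161 CPM (edgeR adjusted p = 0.142; the same adjusted over the list alone). For surface and receptor genes, camera gave adjusted p = 1.20e-04, and adjusted p = 0.559 with an estimated correlation. The sort could have set the Cd34 difference here too. Kit passed with only the 2 types compared, at -0.197 (edgeR adjusted p over its alternatives from 0.00724 to 0.679). edgeR called 10224 of 15004 genes, 5051 higher and 5173 lower in MEP, with 1201 and 3168 at a log2 fold change of at least 1.

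**Figure D3:**
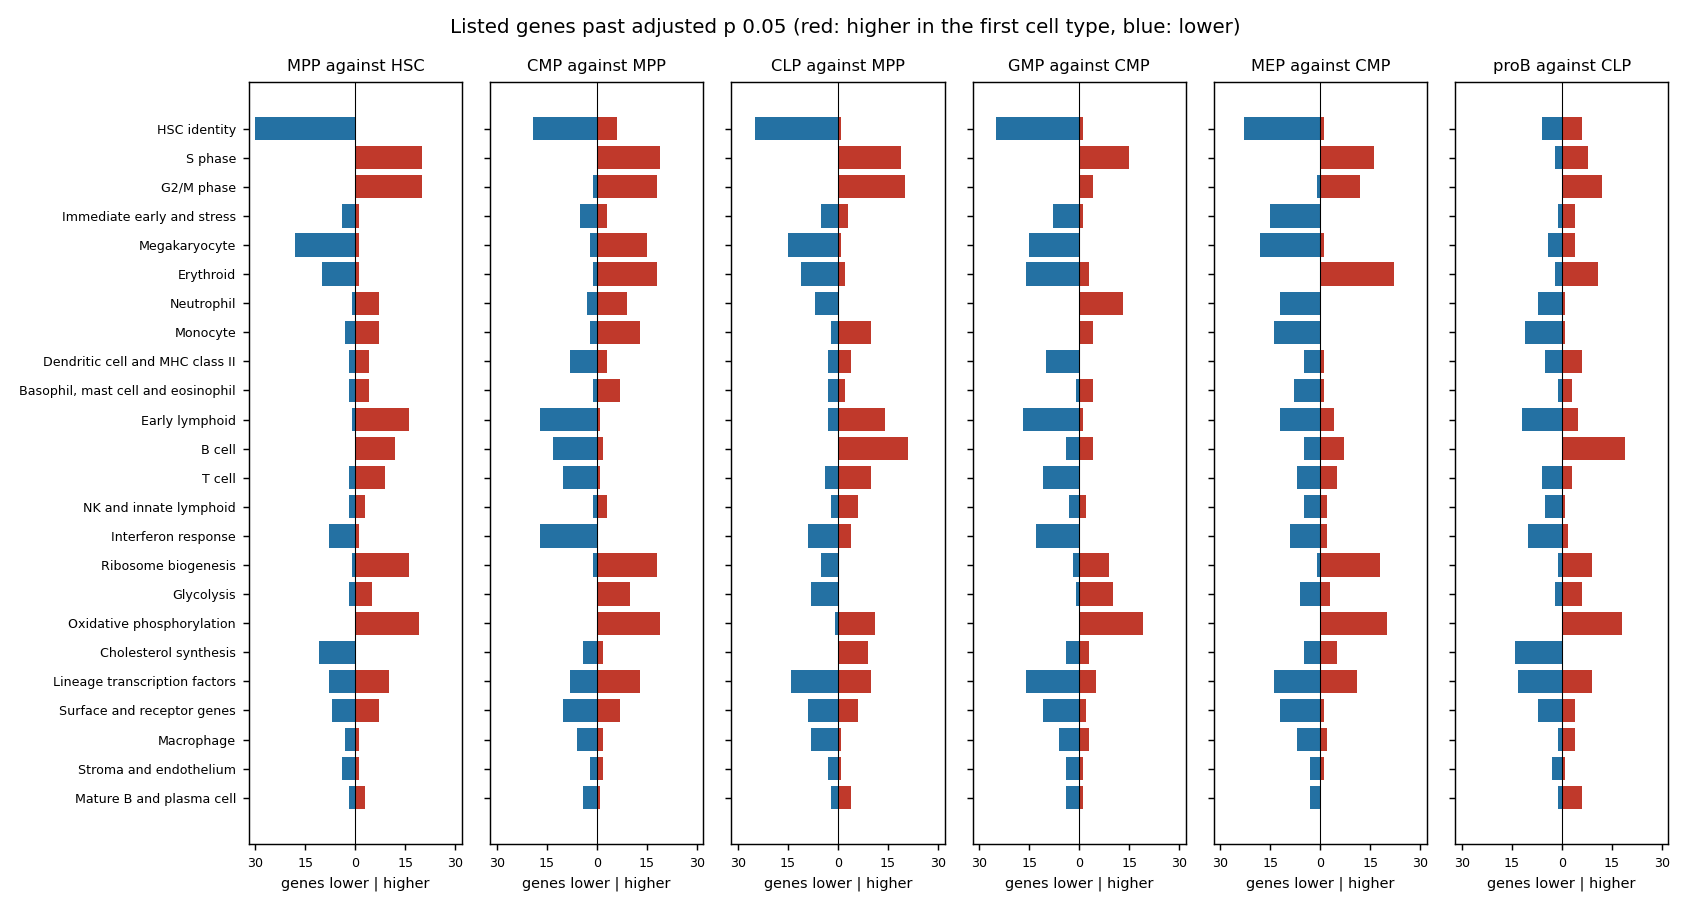
Number of genes of each list past adjusted p 0.05 in the 6 comparisons, lower in the first type to the left (blue) and higher to the right (red). All 30 HSC identity genes are lower in MPP than in HSC, all 21 B cell genes are higher in CLP than in MPP, and all 22 erythroid genes are higher in MEP than in CMP.

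Over the 6 comparisons 70 of 144 list tests passed with the preset correlation. With a correlation estimated for each list 2 did, the B cell list in CLP against MPP and in proB against CLP. The preT library has no replicate, so its genes are given as values with exact 95% Poisson intervals, which cover counting error only. These values are set against CLP and proB of experiment 3, its own experiment, and those of experiment 1 were not used for them. The T cell receptor complex gene Cd3g was at 3612 CPM (3597 to 3626) in preT, and had 0 UMIs in CLP and proB of experiment 3, where the floor of 3 counts is 0.0216 and 0.0910 CPM; it was at least 39696-fold higher than the higher floor. Cd3e was at 444 CPM (439 to 449), also at 0 UMIs in both, and at least 4880-fold higher. Bcl11b, a transcription factor of T cell commitment, was at 592 CPM (586 to 597), with 1 UMI in CLP and 0 in proB. Ptcra, the pre-T receptor alpha chain, was at 356 CPM (352 to 361), against 0.993 CPM (0.834 to 1.17) in CLP and 1.24 CPM (0.892 to 1.69) in proB. Tcf7, an early T lineage factor, was at 566 CPM (561 to 572), against 1.12 CPM (0.947 to 1.31) and 3.49 CPM (2.88 to 4.19). Cd3d, Sh2d1a, Gzma, Khdc1a, Notch3, Ccdc109b, Mpzl2, Aqp11, Themis and Skap1 complete the 15 genes with the highest ratios. Of 21 T cell list genes in the files, 18 were higher in preT than in CLP and proB of experiment 3 with intervals apart, and Cd4, Cd8a and Cd2 were not. Cd4 was at 0.369 CPM and Cd8a at 0.959 CPM in preT. The T cell program was in 99.2% of preT cells, 0.703% ± 0.169 of CLP (SD, n = 2) and 0.0180% of GMP.

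The feature polyexpr, by its name the transcript of the barcode transgene, was found in every library. Its TMM-normalised mean over HSC, MPP and CMP was 32.9, 14.5, 14.7 and 91.8 CPM in experiments 1 to 4 (1 value per experiment). Within an experiment it varied less between cell types: without TMM factors, in single libraries of experiment 4, it was at 111 CPM in HSC, 92.1 in MPP, 91.0 in CMP, 85.1 and 83.7 in the GMP libraries and 112 in MEP. In experiment 3 it was at 17.6 CPM in preT, 15.6 in proB, and 16.9 and 18.5 in the CLP libraries. In cells thinned to 4000 UMIs, 35.1% of HSC had at least 1 UMI of it in experiment 4, and at most 11.8% in the others.

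**Figure D4:**
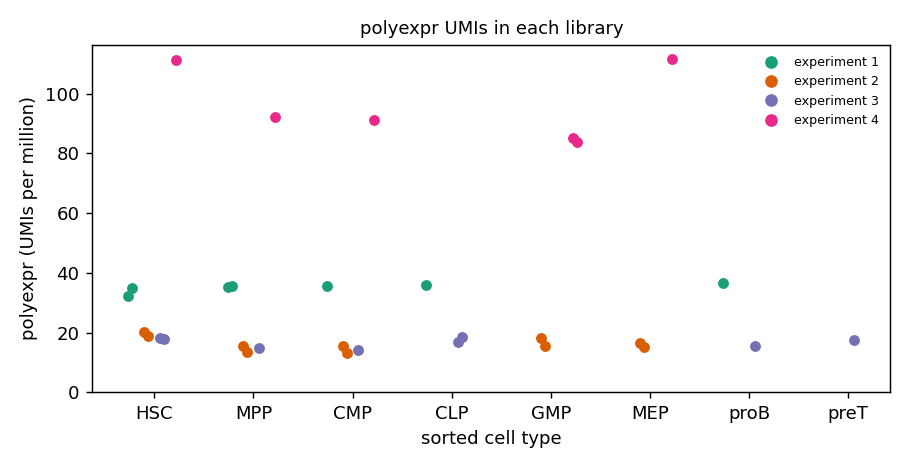
Barcode transcript (polyexpr, CPM) in each library by cell type, coloured by experiment. The libraries of experiment 4 are the highest in each cell type they cover, from 83.7 CPM in a GMP library to 112 CPM in MEP.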

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

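The tests of the neutrophil transcripts in HSC of experiment 4 were chosen after the result was seen. In groups of 4 experiments, a value was singled out when its gap to the nearest other was large for the range of the group. This held in 35 of 299 groups, where independent and normally distributed groups would give about 15 (1 in 20). Many groups are values of the same sums and so are not independent, and the excess over 15 is no test of chance. Of the 35 groups, 29 were in experiment 4, 4 in experiment 3, 2 in experiment 2 and 0 in experiment 1.

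In MPP of experiment 4, lymphoid genes stood over the other experiments: Il7r at 30.07 CPM, Ly6d at 14.76, Rag1 at 3.39, Cd247 at 2.731, Ebf1 at 1.111, Vpreb2 at 0.7345, Igll1 at 0.6026 and Blk at 0.4331. The share of MPP cells with the T cell program was 0.3255%. Other genes also stood high there: Mpo at 209.5 CPM, Cox6a2 at 57.7, Socs2 at 5.518, Ly86 at 4.181 and Csrp3 at 1.488. Tnip3 stood low at 18.95 CPM and Rab27b at 1.996. In HSC of experiment 4, high values were Mycn at 105.6 CPM, Socs2 at 60.72, Mpo at 15.31, Elane at 11.41, Ctsg at 10.55, Il7r at 1.29 and Cox6a2 at 0.3307. Program shares stood high in the same library: monocyte 1.124%, basophil, mast cell and eosinophil 0.2959%, erythroid 0.2071% and T cell 0.08876%. In CMP of experiment 4, Dntt was high at 83.05 CPM and Ltb low at 7.531.

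In experiment 3, MPP stood high in Elane (55.37 CPM), Car1 (9.628) and Igsf6 (1.737) and low in Wfdc18 (20.3). In experiment 2, HSC stood low in Cycs (128.0 CPM) and CMP high in Wfdc21 (0.7189). No explanation of these values was tested.

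The HSC library of experiment 4 held more neutrophil transcripts than the other HSC libraries, with S100a8 at 118 CPM against at most 6.00. Of the 6202 UMIs of S100a8, S100a9, Camp, Ngp and Ltf, a Poisson spread over all cells would give 5.77%, which argues against free RNA as their main source, and 92.0% lay in 5 of 3708 cells with at least 10 (82.6% without the highest cell), so a few cells may be that source. Of the 1283 neutrophil program UMIs other than Prtn3, which hold none of these genes, 55.96% lay in 21 cells with at least 3, 273 in 1 cell and 445 in the other 20, the latter 81.36 times a Poisson spread, which argues against free RNA there; without the 1 cell the share was 44.1%. Free RNA stays open for the 518 cells with 1 or 2 of them: 47 held 2, 1.343 times a Poisson spread and between the 2 bounds. The design gives no group that separates this library, so no biological explanation was tested.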

How the results depend on the processing

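Leaving out HSC of experiment 4, leaving out 3 CMP and GMP libraries, the neutrophil program without Prtn3 and 4 other random draws were chosen after the data were seen. Counts of genes different between types stayed within 1.5 times under every alternative that kept all experiments: 5551 to 9414 for MPP against HSC, 6887 to 10219 for CMP against MPP, 5546 to 8888 for CLP against MPP, 6173 to 9816 for GMP against CMP, 8692 to 11052 for MEP against CMP and 5618 to 8801 for proB against CLP. With an experiment left out, they were 6569 to 7477, 7090 to 8943, 4946 to 8093, 5358 to 7861, 7589 to 9973 and 5687 to 8502. The counts of 4946 (without experiment 1) and 5358 (without experiment 2) leave 1 sum of CLP or GMP, taken to vary like the other types.

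Of 264 gene results examined, 258 passed, and 253 kept their side of the threshold under all alternatives. Among results that passed in the main fit or in the alternative, 0 changed sign. Csf1r in GMP against CMP passed in neither and went from 0.69 to -0.048 without experiment 2. The call was lost without an experiment for 2 and under another setting for 5, and 5 gained it. Fold changes moved by over 1.5-fold for 32 results with an experiment or libraries left out.

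With a correlation estimated for each list, 2 list tests passed in place of 70. Without the experiment term 75 passed, 69 of them among the 70, and the immediate early and stress list in MEP against CMP was lost.

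The exact sign-flip test gave 0 programs past the threshold in CMP against MPP and 0 in MPP against HSC, as did each experiment left out (0 to 0 in both), because these tests cannot reach it at this size. Under the other settings, 8 to 10 and 4 to 8 programs passed. The erythroid program, MPP minus HSC, was reversed at -0.195 points with at least 2 UMIs and -0.663 points without thinning. Megakaryocyte with erythroid cells were at a ratio of 1.08 with at least 2 UMIs, against 0.398. For these, the cause was not tested. Pairs of programs under 1 in all experiments numbered 7 to 8. Depth limits the shares: thinning to 2000 UMIs left 8 programs in CMP against MPP and 4 in MPP against HSC.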

Other observations

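The tests of the cell mixture, of UMIs per cell and of sequencing depth were chosen after the result was seen. Between experiments, edgeR called 6879 of 15004 genes. Mean CPM over HSC, MPP and CMP in experiments 1, 2, 3 and 4 was 1809, 1875, 0.138 and 0.136 for Xist, an X-linked RNA of female cells, and 0, 0.00150, 57.9 and 63.6 for the Y-linked Ddx3y. Rps27 was at 863, 124, 133 and 1512 CPM, Rpl34 at 628, 51.2, 55.4 and 884, and Hist1h2ao at 389, 45.0, 33.1 and 364. Jchain was at 0.266, 7.22, 0.248 and 0.187. These genes were chosen after their values were seen. In every sum of experiments 1 and 2, Xist was at 1086 CPM or more and Ddx3y at 0.00519 CPM or less. In every sum of experiments 3 and 4, Xist was at 0.293 CPM or less and Ddx3y at 56.6 CPM or more. By these genes the cells were female in experiments 1 and 2 and male in 3 and 4. CLP, proB, GMP and MEP thus each have a female and a male sum. For the other genes no explanation was tested. In preT, which was tested in no comparison, the basophil, mast cell and eosinophil program was in 6.88% of cells, and Cpa3 was at 126 CPM, against 2.01 to 3.18 CPM in the CLP libraries.

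The barcode transcript polyexpr was higher in experiment 4 than in the others. Its mean over HSC, MPP and CMP was 32.9, 14.5, 14.7 and 91.8 CPM in experiments 1 to 4. Rps27, Rpl34 and Hist1h2ao were also higher in experiments 1 and 4 than in 2 and 3. Xist, Ddx3y and Jchain did not follow this order, and a shared cause was not tested. Lower sequencing depth and a few cells with many UMIs are argued against by the share of cells with the transcript at 4000 UMIs in every cell, at least 2.486 times the highest other experiment in HSC, MPP and CMP. Fewer UMIs of other genes per cell, with polyexpr unchanged, would raise this share too but leave its UMIs per cell no higher; these were at least 2.014 times the highest other in HSC and CMP, which argues against it for those types. In MPP the ratio was 1.135, between the 2 bounds, so this explanation stays open there; the types were separated after the values over all 3 were seen. No biological explanation was tested.

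The 2 CMP libraries of experiment 2 differed in immediate early genes, with Fos at 152 and 9.68 CPM. A different mixture of cells is argued against by the shares of 5 lineage programs, whose largest absolute log2 ratio between the libraries was 0.1836. Of the listed genes with at least 5 CPM, 15 of 15, 100%, were over 2-fold higher in library 1, but these genes are the pattern itself, so this test decides nothing on a stress response in the handling of 1 library, which stays open. The design does not separate the 2 libraries, so no biological explanation was tested.

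Other splits of the 8 sums into 4 and 4 were set against the 2 counts of genes with 4 experiments per type. The types of an experiment are paired, and 8 of the 35 splits part all 4 pairs, too few for a share under 0.05. The real split gave 7945 genes in MPP against HSC, and the highest other of these 8 gave 1; in CMP against MPP they gave 9186 and 0. The other 27 splits put the 2 types of at least 1 experiment on the same side. With them included, 1 split, the real one, reached the real count in each comparison, and the highest others were 1 and 1607.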
